A study of Mus musculus with 7 samples.

How the data were processed

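Total RNA (1 µg) of plantaris muscle was hybridised to 7 Affymetrix Mouse 430 2.0 arrays, per the labels. Partek is named in the submitters' processing notes with no version or role, and the way probe sets were summarised is not given in the sources used here. The deposited values are intensities on a linear scale. On every array their mean after dropping the lowest and highest 2% of the probe sets is 500, so the authors scaled each array as a whole, with no quantile normalization. Scaling of this kind cannot show whether total RNA per muscle changed. The 3'/5' signal ratios of Gapdh were 0.81 to 0.91 and those of actin 1.10 to 1.20, highest for tamoxifen overload replicate 2 in both.

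The values were taken as log2(value + 1). Each of 34958 probe sets with a single gene symbol in the platform annotation was assigned to its gene, with symbols checked through the Entrez identifier (34754 matched, 204 unmatched, 0 symbols changed). The 64 control probe sets, 932 with several symbols and 9160 without a symbol were not tested as genes. Each of 18193 genes is represented by its probe set with the highest mean over all arrays. The background level, log2 5.82 or a signal of 55.4, is the 95th percentile of the mean level of 74 olfactory, vomeronasal and taste receptor genes. Where one side of a comparison lay at or below it on every array, the fold is given as a bound against that level.

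Groups came from the titles: vehicle sham (n = 1), tamoxifen sham (n = 1), vehicle overload (n = 2) and tamoxifen overload (n = 3). A linear model with a term for each group and a term for sex was fitted with limma 3.58.1 in R 4.3.3 (with the data.table package, version 1.17.8), with variances moderated along an intensity trend. It has 2 residual degrees of freedom and 5.95 prior ones. The sham groups have no replicates, so their arrays were assumed to vary like the overload arrays. Tested were overload against sham (mean of both treatments, and each treatment), tamoxifen against vehicle in overloaded muscle, the interaction, and female against male. All tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over 18193 genes. The sham arrays were compared without a test, against 10000 random gene lists of matched expression (20 bins). SE is the moderated standard error of limma.

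For 47 gene lists (34 of pathways and controls, 13 of cell types; 668 different genes measured, 51 of 751 entries without a measured gene) members were counted over all genes and adjusted over the list alone. Lists were tested with camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, which has 2 degrees of freedom here, and with fry, which tests a list without comparing it with other genes. The groups, lists, comparisons, rules and all but 1 of the alternatives were chosen before the data were examined. The rule for named genes took, per tested comparison, the 10 largest rises and 10 largest falls among called genes above background whose arrays did not overlap between groups, filled up to 5 with genes at an unadjusted p under 0.05 where fewer passed; up to 4 members of each described list with the largest differences; and Pax7, Myod1, Myog, Myf5, Myh3, Col1a1, Col3a1, Xist and Ddx3y throughout.

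The procedure was tested on simulated data: in 10 draws of 18193 genes with 200 changed, a 2-fold change was found for 64.5% of genes for overload against sham, 34.2% within vehicle, 68.1% for tamoxifen against vehicle in overload and 10.1% for the interaction, and a 4-fold change for 92.6%, 85.0%, 94.5% and 69.4%. False genes made up 7.7% to 8.9% of those called, above the nominal 5%, and the simulated noise follows the fitted variances, which makes these figures optimistic. For tamoxifen against vehicle in overload, 1 list shifted by 0.5 (log2) was called by camera with the preset correlation in all 10 draws. On average 1 unshifted list per draw was called too, although the simulated genes vary independently. Alternatives were no sex term, male arrays alone, an additive model, quantile normalization, median centring, a pseudocount of 16, filters on dim genes, a fold minimum of 1.5, every probe set tested, the mean of a gene's probe sets, variances without the intensity trend, an ordinary linear model, overload arrays alone, and leaving out each array in turn. A fit with neither sex term nor intensity trend was added after seeing the data. When either female array (vehicle overload replicate 1 or tamoxifen overload replicate 3) is left out, the sex term takes up the other. For comparisons of the groups these fits are therefore nearly the same as that of male arrays alone, and are not separate checks. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.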

Results

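Gene expression was measured in plantaris muscle of Pax7-DTA mice aged 4 months, on 7 Affymetrix Mouse 430 2.0 arrays. In these mice tamoxifen switches on a toxin in cells that express Pax7, the transcription factor of muscle stem cells (satellite cells). By design tamoxifen treatment is meant to deplete these cells and vehicle treatment to keep them. The muscle was sham operated or overloaded for 1 week by synergist ablation, in which muscles that share the work of the plantaris are removed. There was 1 array of a male for vehicle sham and 1 for tamoxifen sham, 2 arrays for vehicle overload (1 female, 1 male) and 3 for tamoxifen overload (1 female, 2 male). The sample titles read as single mice, while the series' design text speaks of pooled muscles and 11 animals, so how many animals stand behind an array is uncertain. The median signal of an array lay between 88.2 and 127.7. On average over the arrays 12451 of 18193 genes (68.4%) lay above the background level, and the small number of arrays limits the precision of every value.

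The first question was what overload changed in the muscle, averaged over both treatments (5 overload against 2 sham arrays). Genes of the extracellular matrix rose. All 18 collagen chains measured did so, with a median log2 difference of 2.29. Among them Col5a2 rose by 3.39, Col8a1 by 3.36, Col14a1 by 3.21 and Col11a1 by 3.16. The main fibrillar chains Col1a1 and Col3a1 rose by 3.0 ± 0.16 and 2.0 ± 0.16 (log2, SE). Over the alternatives of processing they ranged from 1.983 to 3.151 and from 1.635 to 2.935, wider than the SE. Of 20 matrix glycoproteins and proteoglycans 16 rose (17 when adjusted over the list alone). Postn (periostin) was 42.9-fold higher (adjusted p = 3.74e-06), and Tnc, Bgn and Fn1 rose by 3.02, 2.85 and 2.60. Of 21 genes of collagen processing and matrix turnover 17 rose and 1 fell (18 and 2 when adjusted over the list alone). The protease gene Mmp12 was at least 2.34-fold higher, and Timp1, Mmp14 and Mmp3 rose by 4.12, 3.45 and 3.34. The camera test of limma with a preset correlation called these 3 lists higher (adjusted p from 9.01e-17 to 5.81e-11). For each of them adjusted p = 0.587 with an estimated correlation.

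Markers of connective tissue cells moved with the matrix genes. Of 17 fibroblast and fibro-adipogenic progenitor markers 10 rose and 1 fell (13 and 1 when adjusted over the list alone). Pdgfrl, Mfap5, Pi16 and Fap rose by 2.97, 2.43, 2.31 and 2.08. Of 10 tendon cell markers 5 rose and 1 fell (6 and 1 when adjusted over the list alone). Tnmd rose by 2.09, Kera by 1.62 and Ptx4 by 1.40, while Egr1, at 1.21, did not pass (adjusted p = 0.132), though it did without vehicle overload replicate 1 or tamoxifen overload replicate 3 or 1. Both lists were called higher by camera (adjusted p = 6.64e-07 and 0.00787); with an estimated correlation adjusted p = 0.587 and 0.613.

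Genes of myoblast differentiation and of embryonic and neonatal sarcomeres rose strongly. Their lists share Actc1, Myl4 and Tnnt2. The sarcomere list also shares Ankrd1, Csrp3, Xirp1 and Fhl1 with a list of genes that respond to mechanical load. Whether new muscle formed was not tested. Of 18 genes of myoblast differentiation and fusion 15 rose (15 when adjusted over the list alone), with a median of 2.99. Mymk and Mymx, which encode the membrane proteins that fuse myoblasts, were at least 15.5-fold and at least 7.13-fold higher. Chrng, the fetal acetylcholine receptor subunit, was at least 2.66-fold higher, and the differentiation factor Myog rose by 3.39 ± 0.36. Chrng lost its call in 7 of 18 alternatives. Of 12 embryonic and neonatal sarcomere genes 10 rose (10 when adjusted over the list alone), with a median of 3.14. Mybph rose by 6.31 ± 0.35, Myl4 by 4.75, the embryonic myosin heavy chain Myh3 by 4.73 ± 0.16 and the neonatal one, Myh8, by 4.50. Over the alternatives Myl4 ranged from 2.732 to 4.928. Of 20 satellite cell and myoblast markers 7 rose and 1 fell (7 and 1 when adjusted over the list alone), with Peg3, Cxcr4, Vcam1 and Megf10 at 2.64, 2.50, 2.28 and 2.14. Pax7 itself stood at 0.40 ± 0.81 (adjusted p = 0.781), Myod1 at -0.65 ± 0.34 (adjusted p = 0.222) and Myf5 at 1.28 ± 0.48 (adjusted p = 0.0957), none of which passed. Without the male vehicle overload array (replicate 2) Pax7 came to -0.72 and Myod1 to -1.40, which passed, and Myf5 passed without vehicle overload replicate 1 or tamoxifen overload replicate 3 or 1. Camera gave adjusted p = 2.39e-08, 3.70e-09 and 0.0205 for the 3 lists. With an estimated correlation adjusted p = 0.587 for each.

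Genes of 5 immune lists rose as well. Of 20 macrophage and monocyte markers 18 rose (19 when adjusted over the list alone), with a median of 1.98. Trem2 was at least 6.05-fold higher, Fcgr1 rose from a sham mean below background, and Lgals3 and Cd68 rose by 3.11 and 2.77. Of 22 chemokines and cytokines 11 rose (13 when adjusted over the list alone). Ccl8 rose by 4.63, Cxcl10 from a sham mean below background, and Ccl5 was at least 3.30-fold higher. Cxcl5 passed too, but lay above background on 2 tamoxifen overload arrays alone and lost its call in 10 of 17 alternatives, among them leaving out vehicle overload replicate 2 or tamoxifen overload replicate 2. Of 13 complement and coagulation genes 10 rose (11 when adjusted over the list alone; C1qb by 2.52, Cfb by 2.28). Of 12 antigen presentation genes 10 rose (10 when adjusted over the list alone; H2-Aa by 2.04, Cd74 by 1.88) and of 16 interferon response genes 9 (14 when adjusted over the list alone; Oasl2 by 2.13, Irf7 by 1.79). Camera called all 5 lists higher (adjusted p from 5.84e-14 to 5.09e-05); with an estimated correlation adjusted p = 0.613 for the interferon list and 0.587 for the others. Markers of T, B and natural killer cells (median -0.07; 1 of 12 rose), neutrophils (1.19; 3 of 8) and mast cells and eosinophils (0.56; 1 of 8) were not called as lists (the same member counts when adjusted over the list alone; adjusted p = 0.931, 0.133 and 0.362, and 0.963, 0.614 and 0.613 with an estimated correlation).

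Proliferation and growth genes rose with them. Of 27 cell cycle and DNA replication genes 20 rose and 1 fell (22 and 1 when adjusted over the list alone), with a median of 1.76. The mitotic genes Bub1, Cdk1 and Birc5 were at least 2.09-fold, at least 7.20-fold and at least 4.61-fold higher, and Top2a rose from a sham mean below background. Of 18 growth signalling genes 9 rose and 2 fell (11 and 2 when adjusted over the list alone). The growth factors Igf2 and Igf1 rose by 3.45 and 2.31 and Fstl1 by 2.45, while Smox, a polyamine oxidase, fell by 2.94 on the log2 scale. Camera gave adjusted p = 8.14e-09 and 0.000988. For both, adjusted p = 0.587 with an estimated correlation.

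Genes of energy metabolism fell. Oxidative phosphorylation had 18 of 23 genes lower (23 when adjusted over the list alone; median -0.61; Cox7a1 -1.32, Sdha -0.94) and the tricarboxylic acid cycle 10 of 14 (13 when adjusted over the list alone; median -0.62; Idh2 -1.45, Idh3g -1.10). Fatty acid oxidation and transport had 14 of 16 lower (14 when adjusted over the list alone; median -0.70), among them the regulators Ppara (-1.56) and Ppargc1a (-1.42). Glycolysis and glycogen had 11 of 15 (13 when adjusted over the list alone; median -0.67; Gpd1 -1.83, Fbp2 -1.79). Calcium handling and excitation had 6 of 13 lower (7 lower and 1 higher when adjusted over the list alone; median -0.44; Clcn1 -1.59, Jph1 -1.05), and adipocyte markers 6 of 10 (7 when adjusted over the list alone; median -1.12; Retn -2.11, and Lep, not clearly above background on any array). Camera called these 6 lists lower (adjusted p from 1.05e-10 to 0.000238); with an estimated correlation adjusted p = 0.613 for calcium handling and 0.587 for the others. The mean level of the adipocyte markers was 7.79 to 8.33 on the 3 male overload arrays, against 9.15 and 9.26 on the male sham arrays, and 8.99 and 9.48 on the female overload arrays. After quantile normalization the other 5 medians shrank to -0.33, -0.43, -0.60, -0.41 and -0.20, in the order given, and calcium handling was no longer called (adjusted p = 0.061), while centring on the medians gave -0.98, -0.99, -1.06, -1.03 and -0.81.

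Among fibre type genes, 7 of 14 slow fibre genes rose and 1 fell (7 and 1 when adjusted over the list alone). Sln, an inhibitor of the calcium pump, was 89.6-fold higher, the slow troponin Tnni1 rose by 3.08 and Casq2 by 2.20, while Myl3 fell by 2.49 on the log2 scale. Myl3 lost its call in 8 of 19 alternatives, with values from -3.085 to -1.15. Over the alternatives the log2 rise of Sln ranged from 4.466 to 6.739. Of 14 fast fibre genes 2 fell (1 when adjusted over the list alone), Mylk2 by 1.90 and Mybpc2 by 0.59 on the log2 scale; Mybpc2 lost its call in 10 of 19 alternatives, among them leaving out either vehicle overload array or tamoxifen overload replicate 3. All 14 had negative values, with a median of -0.32 that came to -0.04 after quantile normalization, when the list was no longer called (adjusted p = 0.517). Of 13 denervation and neuromuscular junction genes 7 rose (8 higher and 1 lower when adjusted over the list alone), among them Runx1 by 3.17 and Ncam1 by 3.11. This list shares Runx1, Ncam1, Chrna1, Chrng and Chrnd with the myoblast differentiation list and Sln with the slow fibre list, so these are not separate evidence. Camera gave adjusted p = 0.0126, 0.000469 and 0.0122. With an estimated correlation adjusted p = 0.587, 0.613 and 0.614.

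Over all genes, limma called 2678 genes higher and 1485 lower in overloaded muscle, 662 and 57 of them by at least 4-fold. Among the largest rises, Cthrc1, a secreted matrix protein, was at least 102-fold higher, the collagenase Mmp13 at least 19.4-fold, Lce1f at least 3.82-fold and the kinetochore gene Nuf2 at least 2.73-fold. Mybph was 79.3-fold higher, and C1qtnf3 rose from a sham mean at background. The largest falls were in Slc15a5 (to a mean below background), Inmt (log2 difference -3.51 ± 0.30), Nmrk2 (-3.13 ± 0.20), Neto2 (-2.97 ± 0.25), Timp4 (-2.57 ± 0.35), Tlcd3b (-2.56 ± 0.21) and Hmga2-ps1 (-2.53 ± 0.22), with Rgs9bp at least 1.42-fold and Oprm1 at least 1.26-fold lower. The counts rest on the estimate of the spread, which has 2 residual degrees of freedom. Without the trend of variance with intensity, and with an ordinary linear model, 0 genes passed (6292 had an unadjusted p under 0.05 with the trend). Without the male vehicle overload array (replicate 2) 1924 passed. Centring each array on its median moved the median of all genes by 0.37 and turned the balance to 1626 higher and 3455 lower, and quantile normalization gave 1858 and 1423, so the share of rising genes depends on the scaling.

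**Figure D1:**
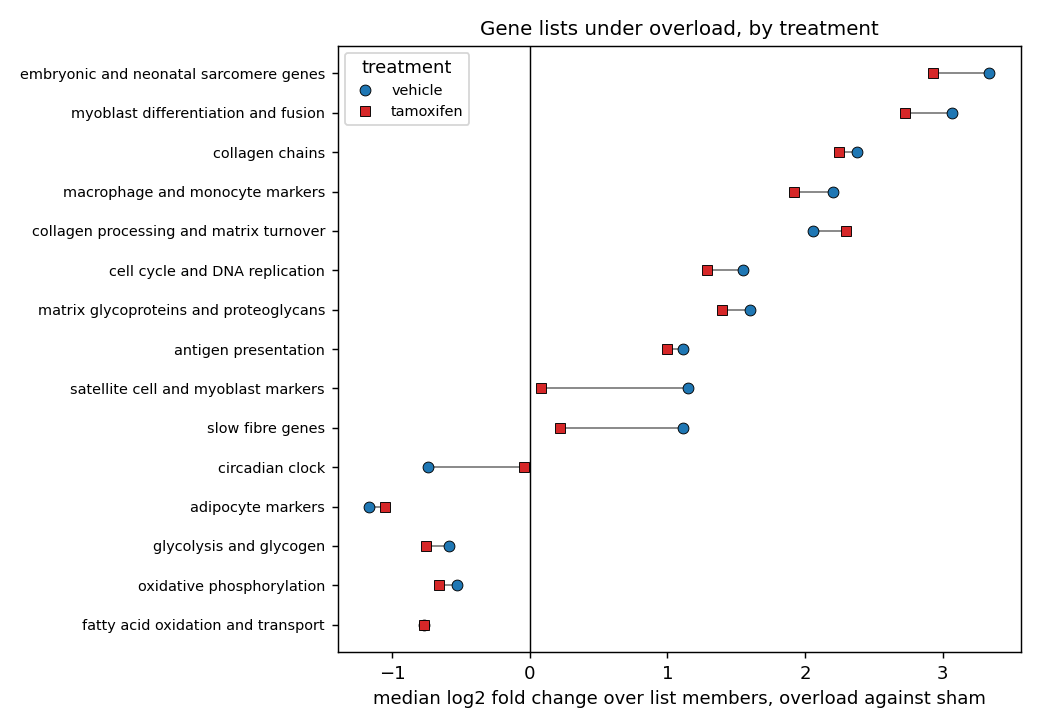
Median log2 difference between overload and sham over the members of 15 gene lists (horizontal axis), for vehicle (circles) and tamoxifen (squares). Embryonic sarcomere genes (3.34 with vehicle and 2.93 with tamoxifen) and myoblast genes (3.07 and 2.73) lay furthest to the right with both treatments, and satellite cell markers lay at 1.15 with vehicle and 0.08 with tamoxifen, the latter turning to -0.09 after quantile normalization and to -0.29 after centring on the medians.

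Overload was next compared with sham within each treatment. With vehicle 1155 genes rose and 444 fell. The largest rises were in Mybph (137-fold), Sln (95.7-fold), Mymk (at least 19.7-fold), Cthrc1 (at least 59.0-fold), C1qtnf3 (at least 55.0-fold), Sh3pxd2b (at least 10.4-fold), the macrophage gene Aif1 (at least 6.87-fold), Mymx (at least 6.12-fold), Lce1f (at least 3.75-fold) and Ltbp2 (at least 3.55-fold). The largest falls were in Nmrk2 (-3.48), Smox (-3.28), Inmt (-3.16), Hmga2-ps1 (-3.12), Neto2 (-3.10) and, to means below background, Slc15a5, Ybx2 and Fgfbp1, with Mmd2 at least 1.48-fold and Foxb1 at least 1.05-fold lower. Foxb1 lost its call in 9 of 17 alternatives, among them leaving out the tamoxifen sham array or vehicle overload replicate 2. Slc15a5 and Fgfbp1 each lost theirs in 7 of 18. With tamoxifen 1815 genes rose and 891 fell. Cthrc1 was at least 146-fold higher, Sln 83.9-fold, C1qtnf3 72.8-fold, Mmp13 at least 32.4-fold, the tenascin gene Tnn at least 10.3-fold, Mymx at least 7.90-fold, Chrng at least 4.73-fold, Piezo2 at least 3.88-fold, Calhm6 at least 3.12-fold and Depdc1a at least 1.70-fold. Over the alternatives the log2 rise of Sln ranged from 4.801 to 6.852 with vehicle and from 4.13 to 6.771 with tamoxifen. Inmt (-3.86), Ces1d (-2.86), Neto2 (-2.83) and Timp4 (-2.80) fell, and Sebox, Ttc22, Gsta3, Crtac1, Gpr26 and Hsd17b14 were lower by at least 4.10-fold, 1.54-fold, 1.52-fold, 1.35-fold, 1.16-fold and 1.03-fold. Hsd17b14 and Crtac1 lost their call in 11 of 17 alternatives, Ttc22 in 9 of 17 and Chrng in 10 of 18, each of them without tamoxifen overload replicate 2. The first 3 also lost it without vehicle overload replicate 1, Hsd17b14 and Chrng without the vehicle sham array, Hsd17b14 and Ttc22 without vehicle overload replicate 2, and Crtac1 and Ttc22 without tamoxifen overload replicate 3 or 1. Crtac1 came to 0.088 with the mean of its probe sets.

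Of the myoblast and sarcomere genes, Myh3 rose by 5.01 ± 0.23 with vehicle and 4.45 ± 0.21 with tamoxifen and Myog by 4.00 ± 0.50 and 2.79 ± 0.46. Of the matrix genes, Col1a1 rose by 3.13 ± 0.22 and 2.87 ± 0.20 and Col3a1 by 2.42 ± 0.23 and 1.58 ± 0.21. Over the alternatives Col3a1 ranged from 2.057 to 3.382 with vehicle and from 1.212 to 2.487 with tamoxifen. Pax7 stood at 1.15 ± 1.14 with vehicle and -0.36 ± 1.04 with tamoxifen, Myod1 at -0.17 ± 0.48 and -1.14 ± 0.44 and Myf5 at 1.33 ± 0.68 and 1.22 ± 0.62, none of them past the test. For tamoxifen, Myod1 passed (-1.39) without either vehicle overload array or without tamoxifen overload replicate 3. For vehicle, Myf5 passed (1.96) without vehicle overload replicate 1 or tamoxifen overload replicate 3. Of the myoblast differentiation and fusion genes 10 of 18 rose with vehicle and 11 with tamoxifen (14 and 13 when adjusted over the list alone; adjusted p = 0.571 and 0.636 with an estimated correlation). The lists of genes called with each treatment shared 881 rising genes, against 115.2 for independent lists, and 363 falling genes, against 21.7; 1 gene was called in opposite directions. Of the genes called with vehicle, 97.8% of the higher and 98.6% of the lower ones had the same sign with tamoxifen, although both lists come from 1 fit with a pooled spread. Each sham side is a single array assumed to vary like the overload arrays. Leaving out either female array gives nearly the same fit here, since the sex term takes up the other one. For vehicle, 371 genes passed without the male vehicle overload array (replicate 2) and 2499 without tamoxifen overload replicate 1, 1023 without vehicle overload replicate 1 and 1022 without tamoxifen overload replicate 3. With median centring the split was 736 higher and 956 lower for vehicle and 1207 and 2105 for tamoxifen, and 0 genes passed for either without the intensity trend or with an ordinary linear model (4370 and 5417 had an unadjusted p under 0.05 with the trend).

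What tamoxifen treatment changed in overloaded muscle was addressed by 3 tamoxifen against 2 vehicle overload arrays. Satellite cell genes had negative values. Pax7 stood at -2.67 ± 0.81 (adjusted p = 0.399), the calcitonin receptor gene Calcr was at least 1.54-fold lower on all 3 tamoxifen arrays, Myf5 stood at -1.35 ± 0.48 and Fgfr4 at -1.09. On the arrays the log2 level of Pax7 was 8.10 and 8.45 with vehicle and 6.92, 5.88 and 3.46 with tamoxifen, against a background level of 5.82. Of the myoblast and sarcomere genes, Myh8 stood at -1.16, Myh3 at -0.75 ± 0.16 (adjusted p = 0.378), Myog at -0.68 ± 0.36 and Myod1 at -0.43 ± 0.34. Without the male vehicle overload array (replicate 2) Myog came to 0.36, Myod1 to 0.56, Myf5 to -0.10 and Myh8 to -0.06. The myoblast differentiation and fusion list overlapped between treatments. Its mean level was 10.49 and 11.802 on vehicle overload replicates 1 and 2, and 11.209, 10.859 and 10.789 on the tamoxifen overload arrays. Metallothioneins Mt2 and Mt1 had the lowest adjusted p of the growth signalling list (-1.22, adjusted p = 0.198, and -1.05, adjusted p = 0.228). No single gene passed. Limma called 0 genes, 1932 had an unadjusted p under 0.05 (1336 higher, 596 lower) where 910 would be expected with no difference. Genes that vary together can give such an excess, so it is not a test. Leaving out an overload array lowers the 2 residual degrees of freedom. Without vehicle overload replicate 2 the comparison rests on 1 female array of each treatment. Without tamoxifen overload replicate 1, 227 genes passed, Mt2, Mt1 and Pax7 among them (Pax7 -3.09, adjusted p = 0.0317, against 0.0317 to 1 over all alternatives).

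Several matrix and immune lists had higher medians on the tamoxifen overload arrays. The array means of matrix glycoproteins, antigen presentation and interferon response genes overlapped between treatments. For matrix glycoproteins vehicle overload replicate 1 (12.699) lay above tamoxifen overload replicate 1 (12.668), and vehicle overload replicate 2 lay lowest (12.044). The main fibrillar chains hardly differed, with Col1a1 at 0.19 ± 0.16 and Col3a1 at 0 ± 0.16 (limma adjusted p = 0.668 and 0.999). All 18 collagen chains had positive values (median 0.36; 0 passed over all genes, 7 when adjusted over the list alone; Col11a1 1.22, Col12a1 1.13), as had 20 of 21 genes of collagen processing (0.54; 0 and 11 when adjusted over the list alone; Timp1 0.94, Ctsk 0.88) and 18 of 20 matrix glycoproteins (0.47; 0 and 5 when adjusted over the list alone; Thbs2 1.12). Macrophage markers had a median of 0.43 (0 and 2 when adjusted over the list alone; Ccr2 0.97, Cd68 0.88), neutrophil markers 1.28 (0 and 4 when adjusted over the list alone; S100a9 2.20, S100a8 1.35, Lcn2 1.46) and chemokines 0.80 (0 and 3 when adjusted over the list alone), Cxcl5 being at least 2.96-fold higher. Oxidative phosphorylation had a median of -0.25, proteasome subunits -0.23, calcium handling -0.37, fast fibre genes -0.21 and satellite cell markers -0.43, each with 0 members past the test, over all genes and when adjusted over the list alone. After quantile normalization these 5 medians came to -0.12, -0.13, -0.29, -0.05 and -0.47 and after centring to -0.40, -0.38, -0.52, -0.36 and -0.59, while that of the collagens came to 0.49 and 0.21. With the preset correlation camera called 19 lists higher and 13 lower, those named here among them (adjusted p from 1.90e-08 to 0.00089); with an estimated correlation 0 lists passed (lowest adjusted p = 0.541), and none did by fry (lowest adjusted p = 0.501). With quantile normalization camera called 18 higher and 7 lower. Without the male vehicle overload array (replicate 2) 19 lists were called, 16 of them also called in the same direction with all arrays, and 28 of the 32 lists kept their direction; myoblast differentiation and fusion was called higher in place of lower. Of the lists named here, collagen chains (adjusted p = 0.0832), matrix glycoproteins (0.375), fast fibre genes (0.222) and satellite cell markers (0.281) were then not called. Col1a1 and Col3a1 aside, each single gene named here but Lcn2 passed without tamoxifen overload replicate 1.

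Beyond the lists, the genes with the largest values that kept the groups apart were Gdpd3 (2.92 ± 0.89), H2-Q10 (vehicle mean below background), Slpi (at least 4.72-fold higher) and Zfp575 (at least 1.19-fold higher), and in the other direction Lix1, Serpinf2 and Dnah6 (at least 1.21-fold, 1.35-fold and 1.13-fold lower); none passed (adjusted p from 0.378 to 0.399), though Gdpd3 and Slpi did without tamoxifen overload replicate 1. Of the 47 lists, 8 had a mean level on all 3 tamoxifen arrays above both vehicle arrays, 11 had it below both and 28 overlapped, where 20% of lists would be expected apart by chance in either direction. The lists lie on the same arrays and some share genes, so a single ordering of the arrays can part many at once. These counts are therefore not a test.

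**Figure D2:**
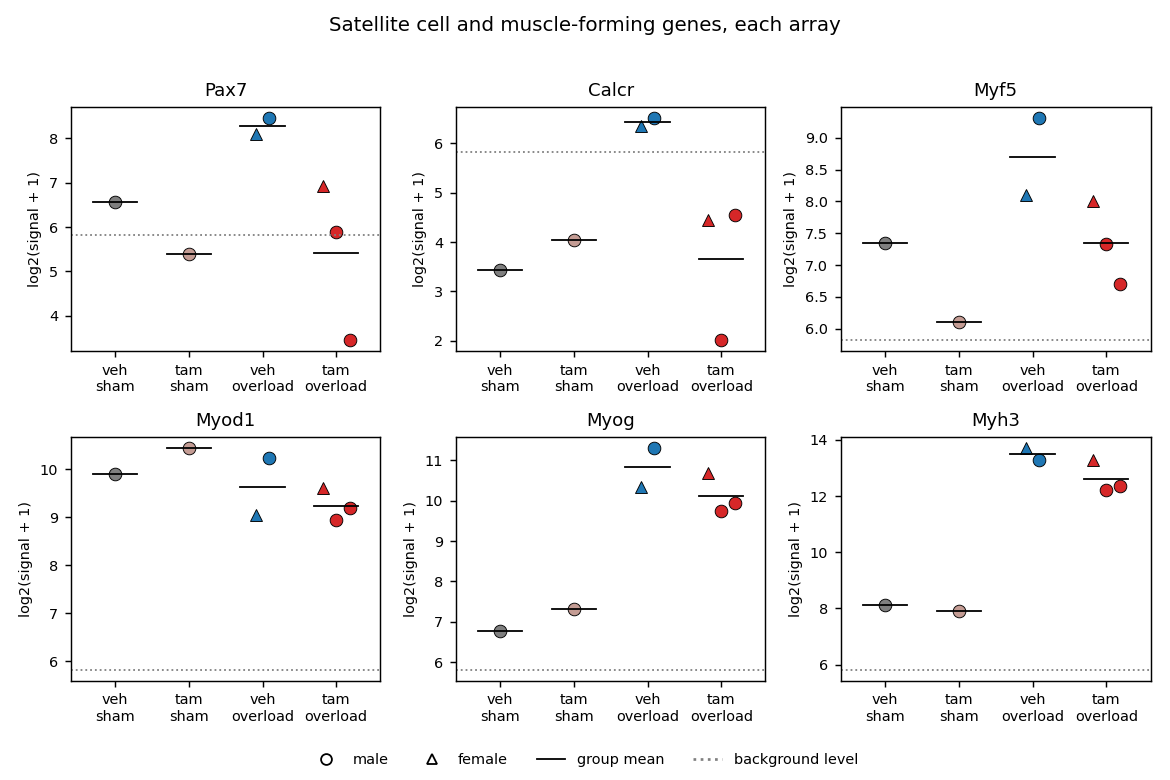
Log2 signal of 6 genes on each array by group (circles male, triangles female, horizontal bars group means, dotted line the background level). Pax7 lay at 8.10 and 8.45 on the vehicle overload arrays and at 6.92, 5.88 and 3.46 on the tamoxifen ones, while Myh3 lay far above its sham level on all 5 overload arrays.

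**Figure D3:**
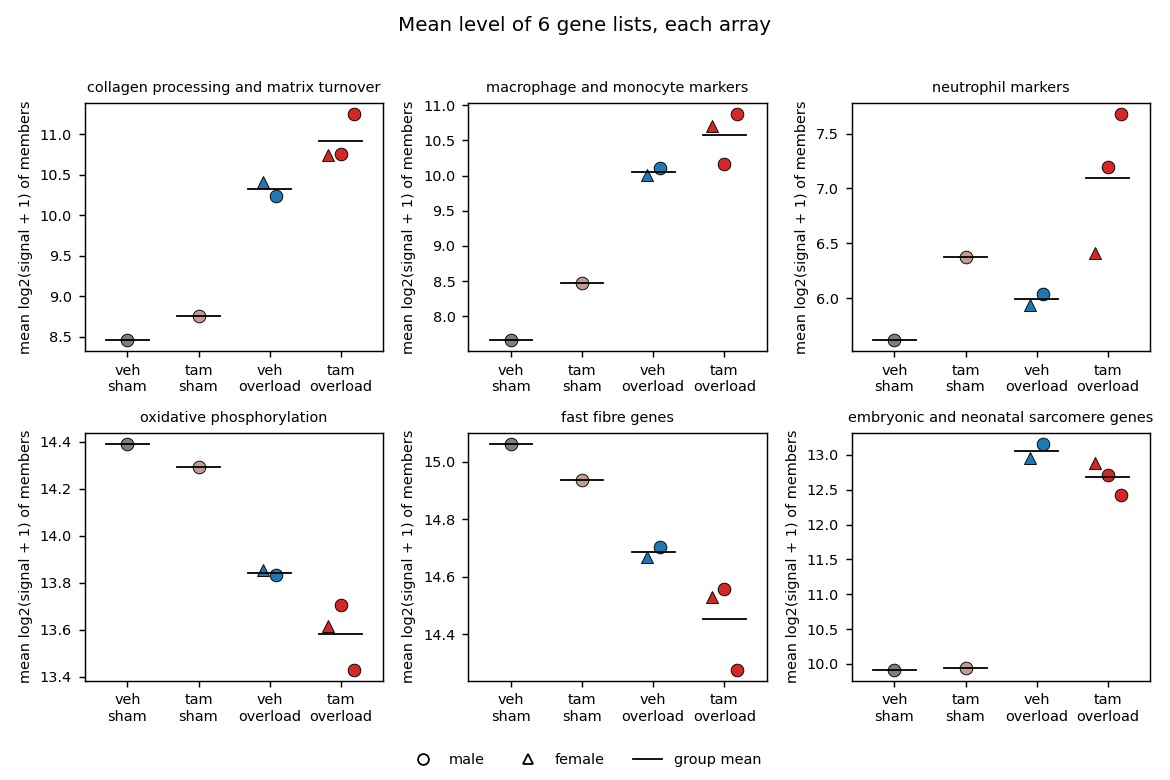
Mean log2 signal over the members of 6 gene lists on each array by group (circles male, triangles female, horizontal bars group means). The 3 tamoxifen overload arrays lay above both vehicle overload arrays for collagen processing, macrophage and neutrophil markers and below both for oxidative phosphorylation, fast fibre and embryonic sarcomere genes. Of all 47 lists, 28 overlapped between these arrays and are not drawn. Between sham and overload the median of the fast fibre genes shrank to -0.04 after quantile normalization.

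Whether the response to overload itself differed between treatments was tested by the interaction. The rule for named genes gave Gsta3, Bmp10, Defb15, Pnoc and Lmx1a with negative values and Gbp2b, Tnn, Abhd16b, Kif17 and Chga with positive ones. Each of them had at least 1 group at or below the background level, so no size is given. Pax7 stood at -1.51 ± 1.47, Myog at -1.22 ± 0.65, Col3a1 at -0.84 ± 0.29 and Mt2 at -2.15 (adjusted p = 0.997, 0.935, 0.784 and 0.245). None passed. Limma called 0 genes and 1021 had an unadjusted p under 0.05, where 910 would be expected with no difference. Both sham sides are single arrays, and in simulated data a true 2-fold interaction was found for 10.1% of genes. Without tamoxifen overload replicate 1, 12 genes passed, Mt2 and Gbp2b among them, and 1 without the male vehicle overload array (replicate 2).

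The sham arrays show resting muscle with either treatment, with 1 array each and no test. Pax7 was at least 1.66-fold and Fgfr4 at least 2.06-fold lower on the tamoxifen array, and Myf5 stood at -1.24, while the satellite cell list as a whole had a median of 0.07, turning to -0.06 after quantile normalization and -0.07 after centring. Antigen presentation genes had a median of 0.69 (H2-Aa 2.21, Cd74 1.88), macrophage markers 0.65 (Ccr2 at least 4.95-fold higher), collagens 0.61 (Col14a1 1.19), matrix glycoproteins 0.47 and slow fibre genes 0.41, each at percentile 100 of 10000 random lists of matched level. Circadian clock genes had a median of -0.74, at percentile 0. The random lists take genes as independent, so lists whose members vary together reach such percentiles more readily. The largest rises were in Gdpd3 (at least 40.2-fold), Sh3pxd2b (2.27), Fam169b (2.06), Gnaz (1.53), Gsta3 (1.52), Ltbp2 (1.43), Lhb (1.34), Lmx1a (1.27), Mcoln2 (1.22) and Aif1 (1.10), each value being the fold reached at least. The largest falls were in Ciart (-3.49) and Dbp (-3.35), and, as the fold reached at least, Kif17 (2.73), Gbp2b (2.57), Tafa4 (1.67), Tgm5 (1.47), Klk1b8 (1.29), Ces2b (1.13), Abhd16b (1.03) and Marco (1.03). In all, 989 genes above background on at least 1 of the 2 arrays differed by 2-fold or more (687 higher, 302 lower). Pairs of arrays within an overload group differed in 639 to 917 genes. The sham split was 571 and 555 after quantile normalization, 613 and 512 after median centring, and 501 and 223 with a pseudocount of 16.

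The sex of the mice, used as a term in the model, gave 6 genes higher and 3 lower in females among the overload arrays (2 female, 3 male). Xist, which silences an X chromosome, rose by 7.11 ± 0.41, and the Y-linked genes Eif2s3y, Uty and Kdm5d were at least 46.9-fold, 10.5-fold and 6.69-fold lower, as the titles' sexes require; Ddx3y was not measured. The other rising genes were Cdo1 (2.18 ± 0.23) and the immediate early genes Fos (2.79 ± 0.24), Nr4a1 (1.92 ± 0.15), Btg2 (1.60 ± 0.14) and Dusp1 (1.54 ± 0.15), with adjusted p from 0.00504 to 0.0276. Cdo1 lost its call in 9 of 17 alternatives, among them leaving out either vehicle overload array or tamoxifen overload replicate 3 or 2. All 18 immediate early genes had positive values (4 passed, 14 when adjusted over the list alone; median 1.00), and all 10 adipocyte markers too (0 passed, 5 when adjusted over the list alone; median 1.01; Retn 2.72, adjusted p = 0.128). Camera gave adjusted p = 1.07e-27 and 1.28e-12 for these lists, and with an estimated correlation adjusted p = 0.752 for both. Xist did not pass in any other comparison. Slc15a5 (at least 1.45-fold lower) and Gbp2b (at least 5.20-fold lower) did not pass (adjusted p = 0.698 and 0.0581). Without tamoxifen overload replicate 1 both passed, as did Retn; Slc15a5 passed without tamoxifen overload replicate 3, Gbp2b without the tamoxifen sham array, and Retn without either vehicle overload array. The count was 37 without tamoxifen overload replicate 1, and 0 without the intensity trend or with an ordinary linear model (911 had an unadjusted p under 0.05 with the trend).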

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

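The tests of explanations in this part were chosen after the results were seen, except the count of other splits of the arrays. In 6 gene lists the response to overload differed between treatments by the camera test of the interaction with a preset correlation. Satellite cell markers (median log2 difference -0.33, adjusted p = 0.0372), myoblast differentiation genes (-0.51, 0.0101), macrophage markers (-0.48, 0.0216), antigen presentation (-0.33, 0.0129) and slow fibre genes (-0.42, 0.0101) had a smaller value with tamoxifen, and circadian clock genes had a positive value (0.57, 0.0372). With an estimated correlation adjusted p = 0.925 for each, by fry 0.978, and limma called 0 genes (1021 at an unadjusted p under 0.05). With quantile normalization only the myoblast and slow fibre lists were still called (adjusted p = 0.0456 for both), without vehicle overload replicate 2 only antigen presentation, slow fibre and clock genes were, and without tamoxifen overload replicate 1 macrophage markers were not (0.0756). Each of these values contains both single sham arrays. Macrophage, antigen presentation and slow fibre lists had positive medians on the tamoxifen sham array against the vehicle one. Macrophage markers also lay higher with tamoxifen in overloaded muscle. The smaller response of these lists cannot be told apart from a difference between the single sham arrays.

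The circadian part goes back to the sham arrays, where 3 of 3 activator genes were higher on the tamoxifen array (mean 1.86) and 9 of 9 output genes lower (-1.68). Array scaling alone is argued against: the activator minus output difference was 3.54 and stayed at 3.38 after quantile normalization. Tamoxifen itself stays open. The same difference among the overload arrays was -0.06 ± 2.67 (95% interval). This interval lies below the sham value of 3.54, the outcome set to argue against tamoxifen. The sham value rests on 1 array against 1 and has no interval, so the 2 values cannot decide it. Activator minus output was -2.74 on the vehicle sham array and 0.80 on the tamoxifen sham array. It was 0.43 and -0.83 on the vehicle overload arrays and -0.58, 0.05 and -0.40 on the tamoxifen overload arrays. A candidate explanation is another clock time at collection, which the labels do not give. With 1 array in each sham group it was not tested and cannot be told apart from an effect of tamoxifen.

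Immediate early genes were higher on the female overload arrays, by 1.13 in mean level, where the highest of the other splits of the 5 arrays (10 in all) gave 0.60. Adipocyte markers were also higher, by 1.13, so more fat tissue in those muscles, the sex of the mice and shared handling cannot be told apart, since the 2 arrays share all of them. RNA degradation stays open too: the mean Gapdh 3'/5' ratio of these arrays was 0.838, and the highest ratio of the male overload arrays 0.91, but the labels name whole-transcript labelling kits, with which this ratio need not follow degradation.

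The tamoxifen overload arrays lay further along the overload response for matrix, immune and metabolic lists by camera with a preset correlation, while with an estimated correlation and by fry 0 lists passed (lowest adjusted p = 0.541 and 0.501). A single array as the cause is argued against for tamoxifen overload replicate 2, without which 25 of the 32 lists were called in the same direction; without vehicle overload replicate 2 this held for 16, and 1 list, myoblast differentiation and fusion, was called in the other direction. A larger response of the same genes cannot be told apart from a shift already present in sham muscle: differences of 3 pairs of tamoxifen and vehicle arrays correlated with the overload response of arrays outside the pair at r = 0.29, 0.24 and 0.44 across 12451 genes, which are not independent, and of 17 lists called the same way in both comparisons all 17 had a sham median and 10 an interaction median in that direction. A lower share of fibre RNA cannot be told apart from either. Its test took 3 forms, the first 2 replaced after their outcome was seen, and none decides it: macrophage minus satellite cell markers (1.05, lowest adjusted p = 0.0717), 45 pairs of cell type lists with moderated variances (1 pair apart, neutrophil and adipocyte markers, 1.33, adjusted p = 0.0071, the outcome set to exclude the explanation, but with a spread pooled over pairs that share lists and taken as exact), and the same pairs with their own variances (0 pairs apart, lowest adjusted p = 0.642, which with 2 residual degrees of freedom could hardly pass).

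Whether the genes called between overload and sham could arise by chance was asked with the 21 splits of the 7 arrays into 5 and 2. No other split gave as many genes as the real one. It gave 4752 in a fit of 2 groups, without terms for treatment or sex, and the highest other gave 4. This 1 of 21 is the smallest share that 21 splits can give. The other splits keep the overload difference in their residual spread, which lowers their counts. The count of splits argues against chance but cannot exclude it. Of 9160 probe sets without a gene symbol, which the gene tests left out, 535 were called between overload and sham (387 higher, 148 lower). Of the 18193 genes 4163 were called. These probe sets lie on the same 7 arrays and are not independent support.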

How the results depend on the processing

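Of the alternatives 1, the fit with neither sex term nor intensity trend, was chosen after seeing the data. Without the intensity trend, and with an ordinary linear model, 0 genes passed in every comparison; with 2 residual degrees of freedom the counts rest on the variance model. With neither sex term nor trend 2877 genes passed for overload against sham, 419 for vehicle and 671 for tamoxifen (4163, 1599 and 2706 as reported). With male arrays alone 1024 genes passed for vehicle and 3 for tamoxifen against vehicle in overload, and with overload arrays alone 1. With quantile normalization 785 passed for vehicle, and with the mean of a gene's probe sets 1051. With every probe set tested there were 7410 calls for overload against sham, 2470 for vehicle, 4609 for tamoxifen and 19 for sex, where more features are tested. Other causes were not tested.

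Leaving out each array gave 1924 to 4695 genes for overload against sham, 371 to 2499 for vehicle, 1954 to 3563 for tamoxifen, 0 to 227 for tamoxifen against vehicle in overload, 0 to 12 for the interaction and 8 to 37 for sex. Overload against sham has no value without either sham array, nor has a treatment without its own, nor the interaction.

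Of the gene lists, 26, 27, 22, 32, 6 and 15 were called for overload against sham, vehicle, tamoxifen, tamoxifen against vehicle in overload, the interaction and sex. With an estimated inter-gene correlation 0 were called in each, and by fry 4, 0, 0, 0, 0 and 0. For the interaction 3 were called with quantile normalization and 15 with male arrays alone. Leaving out each array gave 19 to 34 lists for tamoxifen against vehicle in overload, 6 to 14 for the interaction (14 without vehicle overload replicate 1 or tamoxifen overload replicate 3, 13 without tamoxifen overload replicate 1) and 15 to 25 for sex (25 without tamoxifen overload replicate 2).

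For 209 named gene values 3918 alternatives gave the same verdict in 3395, a weaker one in 465, a stronger one in 44 and the other direction in 14. The fits without either female array and with male arrays alone are nearly the same for comparisons of the groups, but were counted separately. Crtac1 with tamoxifen came to 0.088 and Myod1 with vehicle to 0.89 with the mean of probe sets. Myod1 with vehicle came to 0.33 with male arrays alone, and Pax7 with tamoxifen to 0.021 with no sex term, with or without the trend. Leaving out each array, Pax7 ranged from -0.718 to 1.19 for overload against sham, -0.705 to 1.90 with vehicle and -0.989 to 0.83 with tamoxifen, Myod1 and Myf5 with vehicle from -1.40 to 0.33 and -0.236 to 1.96, and Myod1 and Myog for tamoxifen against vehicle in overload from -1.17 to 0.558 and -1.46 to 0.358. Values that did not pass as reported passed under these alternatives. For overload against sham these were Myf5 and Egr1, with male arrays alone or without vehicle overload replicate 1 or tamoxifen overload replicate 3 or 1, and Myod1, as lower, without vehicle overload replicate 2 or with median centring. Myf5 passed for vehicle without vehicle overload replicate 1 or tamoxifen overload replicate 3, and Myod1 for tamoxifen without either of these or vehicle overload replicate 2, with male arrays alone and with median centring. For sex, Gbp2b, Retn and Slc15a5 passed in 4, 3 and 2 of 17 alternatives. Myh8 passed for tamoxifen against vehicle in overload with male arrays alone, and without tamoxifen overload replicate 1 15 named genes passed there and Mt2 and Gbp2b for the interaction. The cause was not tested. Pax7 for tamoxifen against vehicle in overload kept its direction (-3.78 to -1.18, adjusted p from 0.0317 to 1) and passed without tamoxifen overload replicate 1. Signal over background limits the dim genes: 12451 of 18193 lay above it on average.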

Other observations

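The tests in this part were planned before the data were examined, and no explanation was tested here. Some lists with values for overload against sham were not part of the comparisons described. Of 14 circadian clock genes 3 fell (1 higher and 3 lower when adjusted over the list alone). The median of this list was -0.74 with vehicle and -0.04 with tamoxifen, the vehicle sham array standing apart (activator minus output genes -2.74, against 0.80 on the tamoxifen sham array), and Cry1 lost its call in 10 of 19 alternatives. Of 14 oxidative stress and Nrf2 target genes 2 rose and 6 fell (2 and 7 when adjusted over the list alone): the haem oxygenase gene Hmox1 rose by 1.86, and Gstm1, Sod2 and Nqo1 had values of -1.45, -0.88 and -0.85. The camera test of limma gave adjusted p = 0.0121 and 0.018 (0.0666 for the latter after quantile normalization), and adjusted p = 0.587 for both with an estimated correlation. Of 14 p53 targets 5 rose (6 higher and 1 lower when adjusted over the list alone), among them Cdkn1a by 2.14 and Eda2r by 1.27, while the list was not called (adjusted p = 0.0554, 0.612 with an estimated correlation, 0.0163 after quantile normalization).

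The first principal component held 70% of the variance and parted the sham arrays (-80.6 and -61.8) from the overload arrays (17.3 and 12.2 with vehicle; 37.6, 25.9 and 49.3 with tamoxifen). The highest signal on an array was between 34937 and 56569.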
